A study of Mus musculus with 36 samples.

How the data were processed

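The samples are 36 bulk hypothalamus libraries from 3 inbred mouse strains, the reference strain C57BL/6J, the obesity and diabetes model NZO/HlLtJ and the wild-derived CAST/EiJ. Each strain was kept on a control diet or on a high-fat, high-sugar (HFHS) diet from 6 weeks of age, and tissue was taken at 15 weeks, per the labels' protocols. The labels give 10% fat for the control diet and 44% fat for HFHS, each with fiber, and the basis of these percentages is not given in the sources used here. There are 12 groups of strain, diet and sex with n = 3 libraries each, so a diet contrast in 1 strain compares n = 6 with n = 6, each with 3 females and 3 males. The labels give each library its own number within a group and say nothing further about separate animals, so the p-values measure spread between these samples. Per the labels' protocols, frozen tissue was pulverized, RNA was taken with TRIzol and a bead kit, libraries were made from polyadenylated RNA with KAPA mRNA HyperPrep, and paired reads of 100 bases came from a NovaSeq instrument. Spike-in transcripts were added according to the same protocols and are not analysed here.

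The authors deposited 2 gene tables. Per the file headers, the first holds expected counts, meaning estimated counts per gene in which reads that match several places are shared out. The deposited values of the second are on a log2 scale after a variance-stabilizing transformation (VST) by DESeq2, per the submitters' processing notes. Reads were mapped to GRCm38, per the same notes. The aligner, the counting tool, the annotation release and the use of strand in counting are not given in the sources used here, so levels of antisense or overlapping genes are uncertain. Coordinates are GRCm38 positions as the deposited tables give them. The design assumed whole counts; 21.4% of the values were not whole, and the expected counts were rounded before testing, which moved library totals by at most 0.00019%.

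Everything else was computed here from those tables. Of 24265 genes, 20053 passed the expression filter of edgeR and were tested. Every gene in the deposited table was above 0 in at least 19 of the 36 libraries. Genes detected in fewer, such as those found in a single strain alone, are therefore missing from the counts of calls. The test was the edgeR quasi-likelihood F-test with TMM normalization on the 12 group means, which leaves 24 residual degrees of freedom. All adjusted p-values for genes come from edgeR unless another tool is named, and are adjusted by the Benjamini-Hochberg method over all tested genes of the contrast. A gene is called at adjusted p under 0.05. Log2 changes are the edgeR estimates, given ± standard error. Log2 CPM levels, as in the principal components and the mean levels of lists, use a prior count of 2. Levels are counts scaled to a common library total (CPM), given as mean ± SD over libraries. Strain contrasts use the control diet only. Sex contrasts are female less male, averaged over the diets. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

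Gene lists were fixed by name, 38 in number, and tested with the camera function of limma at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Beside each list stand the count of member genes called over all genes and the count when adjusted over the list alone. The camera test was repeated with an estimated correlation in place of the preset value. With that estimate, 1 list call remained for diet in NZO/HlLtJ, 1 in CAST/EiJ, 1 for diet averaged over the strains, 1 for NZO/HlLtJ against C57BL/6J, and 3, 2 and 1 for sex in C57BL/6J, NZO/HlLtJ and CAST/EiJ. None remained for diet in C57BL/6J or for either contrast with CAST/EiJ of the strains on control diet. Statements that a list rose or fell refer to the preset correlation unless the estimate is given.

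The contrasts, the filter, the normalization, the test, the lists, the threshold and a set of alternatives to each were chosen before the data were examined. The alternatives are median-ratio size factors, DESeq2, limma on the deposited VST values, no filter, a strict filter of 1 CPM in 18 libraries, an additive sex term, 2 surrogate variables, exclusion of genes above 1% of counts, fits on only the libraries compared, and each library left out in turn. Alternatives added after the data were seen leave out 1 library rich in pituitary transcripts, or add a term for library number in C57BL/6J, the level of red-cell transcripts, or the dependence of level on transcript length. Transcript lengths and gene types come from GENCODE M21, in which 24108 of the gene identifiers were found.

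Genes are named by rule. In each contrast these are called genes with an assigned symbol and a mean of at least 1 CPM, up to the 10 with the smallest p in each direction (autosomal genes for sex) or the 10 with the smallest p for joint tests, and up to 4 members of a list under discussion. Of the genes this rule picks, 1 is not used here. Where no gene passes, up to 5 with the smallest p are given as not passing. Feeding and neurosecretory genes, fixed before testing, are given for diet and strain contrasts whatever their p. Exceptions chosen after values were seen are Cirbp and Rbm3, red-cell, hormone and immediate early genes given outside the contrast that called them, and markers used to test explanations. A test on simulated counts with known changes was run before the contrasts. The counts were drawn from the fitted means and spread of the real genes, independently for each gene and library. Bias shared by the genes of a library was therefore absent from it. In this simulation, edgeR recovered 77%, 82% and 76% of genes changed 1.5-fold, and 95%, 94% and 95% of genes changed 2-fold, in C57BL/6J, NZO/HlLtJ and CAST/EiJ in that order, with 5, 3 and 8 false calls.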

Results

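Strain set the largest differences between the libraries. The top axis of a principal component analysis carried 42.9% of the variance, the next 13.3% and the one after 5.29%. Library totals ran from 23.9 to 47.3 M counts with a median of 34.6 M. Mitochondrial transcripts made up 4.09% to 6.16% of counts, and no gene exceeded 1.87% in any library. The common biological coefficient of variation between replicates was 12.1%.

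**Figure D1:**
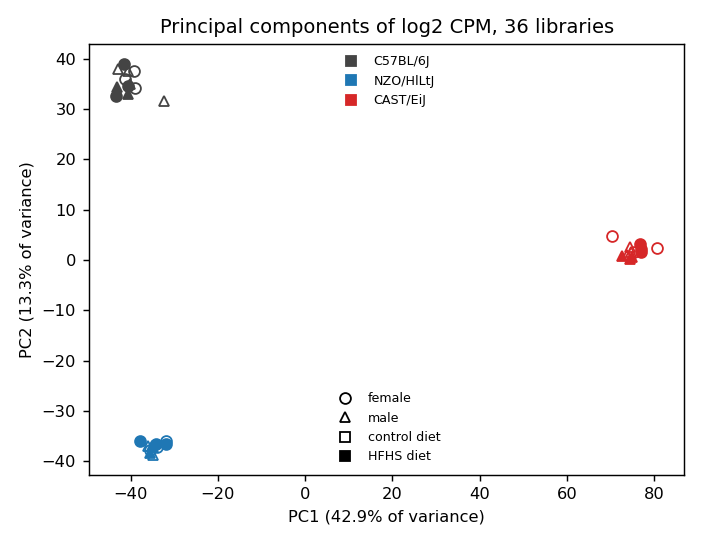
Principal components of the 36 hypothalamus libraries, by strain, diet and sex. Circles are females and triangles males, open points control diet and filled points HFHS.

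Marker genes separated C57BL/6J from the other strains and females from males. Nnt, a mitochondrial proton pump gene with a deletion in C57BL/6J, lay at 21.2–26.4 CPM in the 12 C57BL/6J libraries, 34.8–39.8 CPM in NZO/HlLtJ and 35.3–42.8 CPM in CAST/EiJ. Gabra2, a receptor subunit gene with an intronic deletion in C57BL/6J, lay at 69.2–97 CPM there, against 151–199 and 160–202 CPM in NZO/HlLtJ and CAST/EiJ. These ranges overlap, so neither gene tells NZO/HlLtJ from CAST/EiJ. Xist, the RNA of the inactive X, was at 573–1230 CPM in females and 0.11–2.12 CPM in males, while the Y-linked Ddx3y was at 80.4–114 CPM in males and at most 2.58 CPM in females.

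In NZO/HlLtJ, heat shock transcripts were lower on the HFHS diet. Hspa1b, an inducible HSP70 chaperone gene (GRCm38 chr17 34956436–34959238), was at 4.75 ± 0.758 CPM against 28.9 ± 15.5 CPM on control diet, a log2 change of −2.55 ± 0.38 (adjusted p = 0.00272, n = 6 and 6). The highest HFHS library had 5.73 CPM of Hspa1b and the lowest control library 15 CPM, so all 6 HFHS libraries lay below all 6 controls. Its neighbour Hspa1a (chr17 34969190–34972156) fell to 0.336 of the control level, from 43.7 ± 18.4 to 14.4 ± 1.12 CPM (adjusted p = 0.00272), with allocation of reads between these near-identical copies uncertain. The co-chaperone genes Hsph1 (log2 change −0.61 ± 0.10; 302 ± 10.5 against 461 ± 49.2 CPM, adjusted p = 0.00448) and Dnajb1 (−0.87 ± 0.15; 53.3 ± 4.14 against 98.1 ± 23.8 CPM, adjusted p = 0.00866) were lower as well. Fkbp4, a steroid receptor co-chaperone gene, changed by −0.32 ± 0.07 log2 (adjusted p = 0.0335) and the small heat shock gene Hspb1 by −0.99 ± 0.21 (adjusted p = 0.0366). Fosb, an immediate early gene, fell to 0.244 of the control level, from 11.5 ± 3.7 to 2.94 ± 1.08 CPM (adjusted p = 0.0444). Its level was 10.5–15.7 CPM in the 4 lower-numbered control libraries, 8.18 and 6.7 CPM in control male 3 and control female 3, and 1.82–4.46 CPM in the 6 HFHS libraries. The zinc finger gene Prdm15 changed by −0.38 log2 (adjusted p = 0.0366).

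Serpina3n and C4b were among the 21 genes higher on HFHS in NZO/HlLtJ. Serpina3n, a protease inhibitor gene raised in reactive astrocytes (chr12 104406729–104414329), rose 1.58-fold over both sexes, from 84.8 ± 25 to 135 ± 41.9 CPM (log2 change 0.66 ± 0.11, adjusted p = 0.00448, n = 6 and 6). By sex, females went from 65.5 ± 12 to 170 ± 22.8 CPM and males from 104 ± 17.6 to 100 ± 13 CPM (n = 3 each). Reads of this gene are uncertain in allocation because the Serpina3 family has close copies. The complement gene C4b (chr17 34728380–34743882) rose 1.37-fold, from 301 ± 65.5 to 414 ± 58.6 CPM (adjusted p = 0.0335). Further increases were Mir22hg, a microRNA host gene (1.36-fold; 12.2 ± 0.664 against 8.92 ± 0.837 CPM, adjusted p = 0.00866), the membrane protein gene Stom (1.36-fold, adjusted p = 0.0111), Adamtsl1 (1.51-fold, adjusted p = 0.0118), the receptor gene Gpr146 (1.2-fold, adjusted p = 0.0229), Rsrp1 (1.34-fold, adjusted p = 0.0248), the scavenger receptor gene Scara3 (1.71-fold, adjusted p = 0.0297), the matrix protease gene Mmp2 (1.52-fold, adjusted p = 0.0335) and Eml3 (1.28-fold, adjusted p = 0.0335). In all, 29 genes were called, the other 8 lower. The balance was 23 higher and 8 lower with median-ratio size factors. It was 13 and 15 with 2 surrogate variables, and 79 and 94 on the libraries compared alone. The count moved with single libraries: it was 13, 11, 7 and 14 without control female 1, control female 2, control male 1 and control male 2, and 10, 11, 9, 9, 7 and 19 without HFHS female 1, female 2, female 3, male 1, male 2 and male 3. Without CAST/EiJ control female 1, a library outside this contrast, the count was 98. Hspa1b, Hspa1a and Hsph1 remained called in every alternative fit.

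**Figure D2:**
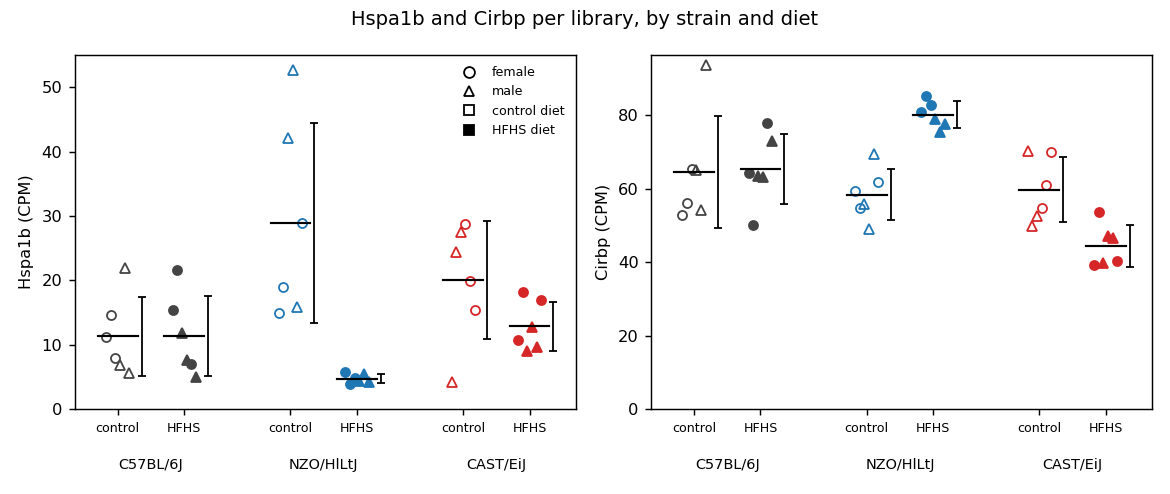
Hspa1b and Cirbp levels by strain and diet. Circles are females and triangles males, open points control diet and filled points HFHS; line, mean; bar, SD of 6 libraries.

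Among the gene lists in NZO/HlLtJ, the 15 heat shock genes fell on HFHS with a median log2 change of −0.318 (adjusted p = 3.68e-32, and adjusted p = 0.0202 with an estimated correlation). In this list 5 genes were called lower, and 13 when adjusted over the list alone. The 20 unfolded protein response genes had a median of −0.183, with 0 called and 12 lower when adjusted over the list alone (adjusted p = 3.62e-09, and adjusted p = 0.201 with an estimated correlation). In this list are the endoplasmic reticulum chaperone genes Sdf2l1 (−0.62 log2, adjusted p = 0.0856) and Hspa5 (−0.35), which did not pass over all genes. The 15 antigen presentation genes were higher with a median of 0.247, 0 called and 6 higher when adjusted over the list alone (adjusted p = 1.77e-08, and adjusted p = 0.201 with an estimated correlation), among them H2-Ab1 at 0.93 and Tap1 at 0.43 log2. Its mean log2 level was −0.301 and −0.343 in control female 1 and control male 1, 0.31 to 0.495 in the other 4 controls and 0.393 to 0.902 in the 6 HFHS libraries. The same 2 libraries were lowest in endothelial markers (−0.135 and −0.183) and in pericyte, vascular muscle and fibroblast markers (−0.382 and −0.806). The 14 endothelial markers had a median diet change of 0.163, with 1 called higher and 1 when adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.539 with an estimated correlation). The 16 pericyte, vascular muscle and fibroblast markers had one of 0.209, with 0 called and 0 when adjusted over the list alone (adjusted p = 0.000105, and adjusted p = 0.539 with an estimated correlation). With 2 surrogate variables neither the endothelial markers (adjusted p = 0.638) nor the pericyte, vascular muscle and fibroblast markers (adjusted p = 0.817) were called. For the 14 reactive gliosis genes the median was 0.329, with 1 called higher and 1 lower over all genes and 8 higher and 1 lower when adjusted over the list alone (adjusted p = 5.84e-06, and adjusted p = 0.201 with an estimated correlation). Its mean log2 level was −0.022 to 0.138 in control female 1, control female 2 and control male 1, 0.586 to 0.684 in the other 3 controls and 0.41 to 0.858 in the 6 HFHS libraries. Gfap, the astrocyte filament gene, had a log2 change of 0.49 that did not pass (adjusted p = 0.3). Myelin genes had a median of 0.216, with 0 called and 0 when adjusted over the list alone (adjusted p = 1.23e-06, and adjusted p = 0.539 with an estimated correlation). Microglial genes had a median of 0.0954, also with 0 called and 0 when adjusted over the list alone (adjusted p = 0.00044, and adjusted p = 0.539 with an estimated correlation), and were not called with 2 surrogate variables (adjusted p = 0.055). The 20 immediate early genes had a median of −0.244, with 1 called lower and 4 when adjusted over the list alone (adjusted p = 5.11e-07, and adjusted p = 0.539 with an estimated correlation). This group moved with library number: its mean log2 level was 0.01 to 0.30 in the 4 lower-numbered controls, −0.45 and −0.35 in control male 3 and control female 3, and −0.58 to −0.32 in the 6 HFHS libraries. Cholesterol synthesis genes had a median of −0.111, with 0 called and 4 lower when adjusted over the list alone (adjusted p = 2.25e-06, and adjusted p = 0.427 with an estimated correlation).

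In CAST/EiJ, red-cell transcripts were lower on HFHS. The beta-globin gene Hbb-bs (chr7 103826534–103828096) was at 97.4 ± 18.1 CPM against 417 ± 191 CPM on control diet, a log2 change of −2.00 ± 0.23 (adjusted p = 1.08e-05, n = 6 and 6). Its HFHS libraries ran from 72.3 to 127 CPM and its control libraries from 190 to 671 CPM, so all 6 lay below all 6 controls. The alpha-globin gene Hba-a2 (chr11 32296489–32297298) changed by −2.00 ± 0.22 log2, from 616 ± 306 to 142 ± 23.2 CPM (adjusted p = 1.06e-05), and Hbb-bt by −2.16 ± 0.26 (adjusted p = 1.96e-05). Globin copies are near-identical, so allocation of reads among them is uncertain. Alas2, the heme synthesis enzyme gene of red-cell precursors, fell to 0.254 of the control level, from 16.3 ± 9.36 to 3.65 ± 0.877 CPM (adjusted p = 0.000108). The ubiquitin-conjugating enzyme gene Ube2l6 fell to 0.558 of the control level (7.14 ± 1.92 to 3.88 ± 0.516 CPM, adjusted p = 0.000208). With these, Cidea, a lipid droplet gene, changed by −0.84 log2 (adjusted p = 0.0184), Fam46c by −0.82 ± 0.17 (adjusted p = 0.0394), Actb to 0.844 of the control level (adjusted p = 0.0337) and the ribosomal gene Rplp0 to 0.838 (adjusted p = 0.0429). The growth hormone gene Gh was at 0.605 ± 1.32 CPM against 155 ± 320 CPM (adjusted p = 0.0349), a control mean carried by the library of control female 1 at 802 CPM.

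**Figure D3:**
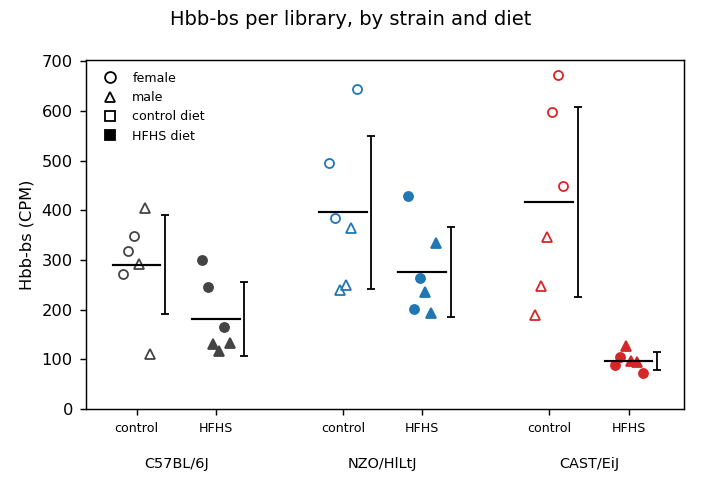
Hbb-bs levels by strain and diet. Circles are females and triangles males, open points control diet and filled points HFHS; line, mean; bar, SD of 6 libraries.

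Reln, Magi2 and Gfra1 were among the 8 genes higher on HFHS in CAST/EiJ. Reln, encoding the secreted glycoprotein reelin, rose 1.43-fold, from 69.1 ± 7.29 to 98.9 ± 8.24 CPM (log2 change 0.52 ± 0.10, adjusted p = 0.0203, n = 6 and 6). The synaptic scaffold gene Magi2 rose 1.18-fold (92.3 ± 7.15 to 108 ± 3.58 CPM, adjusted p = 0.00721) and Gfra1, a GDNF receptor gene (chr19 58235604–58455909), 1.23-fold (55.2 ± 4.39 to 68 ± 5.15 CPM, adjusted p = 0.0349). Log2 changes of the kinase gene Dclk3 (0.33, adjusted p = 0.0444), the transcription factor gene Elk1 (0.32, adjusted p = 0.0444), and the cilium transport genes Ttc21b (0.30, adjusted p = 0.0444) and Ift172 (0.19, adjusted p = 0.0452) were smaller. In all, 24 genes were called, the other 16 lower. With the transcript-length covariate 7 were called, 1 of them higher. Without control female 2 the count was 2681 and without control female 3 it was 135. It was 9, 8, 7, 8, 12, 7, 12 and 8 without control female 1, control male 2, HFHS female 1, female 2, female 3, male 1, male 2 and male 3 in that order. Reln was not called without HFHS female 1, HFHS female 2 or HFHS male 3 (adjusted p = 0.067, 0.0753 and 0.0616), and Gfra1, Dclk3, Elk1, Ttc21b, Ift172, Cidea, Actb, Gh, Fam46c and Rplp0 were not called without control female 1.

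Of the CAST/EiJ lists, the 9 blood genes fell on HFHS with a median log2 change of −2.00, 4 called lower and 6 when adjusted over the list alone (adjusted p = 3.43e-18, and adjusted p = 0.00639 with an estimated correlation). The 45 cytosolic ribosomal genes had a median of −0.22, with 1 called lower and 42 when adjusted over the list alone (adjusted p = 1.66e-23, and adjusted p = 0.367 with an estimated correlation). For the 40 oxidative phosphorylation genes the median was −0.172, with 0 called and 32 lower when adjusted over the list alone (adjusted p = 1.27e-17, and adjusted p = 0.367 with an estimated correlation). Myelin genes had a median of −0.408, with 0 called and 12 lower when adjusted over the list alone (adjusted p = 1.91e-10, and adjusted p = 0.367 with an estimated correlation). Mag, a myelin glycoprotein gene in that list, changed by −0.45 log2 without passing (adjusted p = 0.0812). Tanycyte genes had a median of −0.338, with 0 called and 6 lower when adjusted over the list alone (adjusted p = 0.000544, and adjusted p = 0.367 with an estimated correlation). Pituitary hormone genes had a median of −0.904, with 1 called lower and 6 when adjusted over the list alone (adjusted p = 0.000338, and adjusted p = 0.367 with an estimated correlation). These groups moved with the library of control female 1, which held 1331 CPM of the prolactin gene Prl. In it ribosomal genes stood 0.71 log2, oxidative phosphorylation genes 0.62 and myelin genes 1.14 above the other CAST/EiJ libraries. Relative to the strain's mean over its 12 libraries, level fell with transcript length in that library, by 0.239 log2 per doubling of length. In control female 3 it fell by 0.116, against slopes of −0.0123 to 0.0647 in the other 10 CAST/EiJ libraries. With the transcript-length covariate the oxidative phosphorylation (adjusted p = 0.306) and pituitary (adjusted p = 0.477) lists were not called, and without control female 1 the pituitary list was not called (adjusted p = 0.0735). GABA genes had a median of 0.199, with 0 called and 1 higher when adjusted over the list alone (adjusted p = 0.00355, and adjusted p = 0.367 with an estimated correlation).

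**Figure D4:**
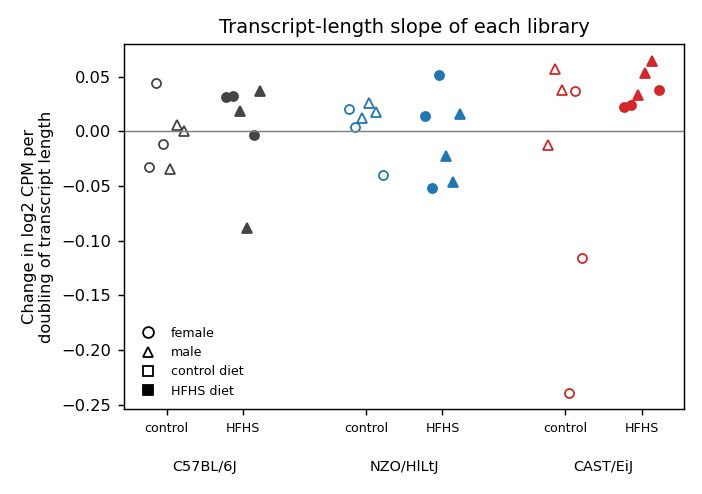
Change in log2 CPM, relative to the mean of the library's strain, per doubling of transcript length, by library. Circles are females and triangles males, open points control diet and filled points HFHS.

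In C57BL/6J no gene passed for diet. The genes with the smallest p, none passing, were the zinc finger gene Zfp950 (log2 change 1.48), the endocytosis gene Ehd3 (−0.18), Zswim3 (0.30), the melanin-concentrating hormone receptor gene Mchr1 (−0.32) and the insulin-degrading enzyme gene Ide (−0.47). The edgeR count was 0, with 687 genes at unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma on VST values. It became 2 without control male 2. Npy, the feeding peptide gene, was at 11.6 ± 2.55 CPM against 20 ± 3.44 CPM on control diet (log2 change −0.78 ± 0.23, adjusted p = 1, adjusted p = 0.015 over the list alone, n = 6 and 6). Its list of 9 orexigenic genes had 0 called and 1 lower when adjusted over the list alone, and was not called (adjusted p = 0.339). Immediate early genes had a median of −0.366, with 0 called and 0 when adjusted over the list alone (adjusted p = 3.86e-08, and adjusted p = 0.522 with an estimated correlation). For the 18 glucocorticoid-induced genes the median was −0.243, with 0 called and 0 when adjusted over the list alone (adjusted p = 2.33e-08, and adjusted p = 0.522 with an estimated correlation). The 9 blood genes had a median of −0.737, with 0 called and 4 lower when adjusted over the list alone (adjusted p = 5.13e-08, and adjusted p = 0.312 with an estimated correlation). A term for library number was added, with a dividing point chosen from these very levels. With it the immediate early genes (adjusted p = 3.9e-06) and the glucocorticoid response (adjusted p = 0.00512) took the opposite sign. The list of blood cell markers was not called with it (adjusted p = 0.898). The dividing point overlaps with diet, since of the higher-numbered libraries only control male 3 was on control diet. That fit therefore does not establish a direction. Antigen presentation genes had a median of 0.156, with 0 called and 0 when adjusted over the list alone (adjusted p = 5.29e-06, and adjusted p = 0.522 with an estimated correlation).

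Averaged over the strains, 6 genes were lower on HFHS and none higher. Hba-a2 fell to 0.481 of the control level (461 ± 226 to 219 ± 92.5 CPM, adjusted p = 2.06e-05, n = 18 and 18), Hbb-bs to 0.477 (368 ± 154 to 185 ± 98.7 CPM), Hbb-bt to 0.432 and Alas2 to 0.461 (adjusted p = 7.74e-05). Ube2l6 fell to 0.763 of the control level (adjusted p = 0.0085) and Hspa1b to 0.473 (20.1 ± 12.7 to 9.68 ± 5.39 CPM, adjusted p = 0.0462). The averaged fall of Hspa1b was not seen in C57BL/6J, where its median was 9.55 CPM on control diet and 9.74 CPM on HFHS. Its median went from 24 to 4.64 CPM in NZO/HlLtJ and from 22.2 to 11.8 CPM in CAST/EiJ. The blood list had a median of −1.05, with 4 called lower and 6 when adjusted over the list alone (adjusted p = 4.29e-32, and adjusted p = 0.000164 with an estimated correlation). The heat shock list had a median of −0.151, with 1 called lower and 12 when adjusted over the list alone (adjusted p = 3.61e-21, and adjusted p = 0.0711 with an estimated correlation), and was not called with the red-cell covariate (adjusted p = 0.861).

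The diet change differed most between NZO/HlLtJ and CAST/EiJ. The difference in log2 change was 0.50 for the linker histone gene H1f0 (chr15 79028212–79030498; SE 0.075, adjusted p = 0.00285, n = 6 in each of 4 groups) and 1.10 for Hist1h1c (SE 0.167, adjusted p = 0.00285). For Serpina3n it was 0.85 (SE 0.152, adjusted p = 0.00926), for Cidea 1.14 (SE 0.206, adjusted p = 0.00926), for Gfra1 −0.49 (SE 0.084, adjusted p = 0.009) and for Reln −0.69 (SE 0.137, adjusted p = 0.0174). In this contrast 361 genes were called, 193 with the more positive change in NZO/HlLtJ and 168 with the more positive change in CAST/EiJ. The count ran from 78 to 215 without any of 17 libraries and was 2211 without CAST/EiJ control female 2. With the transcript-length covariate it was 37, with Reln, Magi2, Tacr1, Dtx4, Elfn1 and Hpcal4 no longer called, and with 2 surrogate variables it was 45. It moved by less without control female 3, control male 3 and HFHS male 3 of NZO/HlLtJ and control female 1, control female 3 and control male 3 of CAST/EiJ.

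Contrasts of the diet change with C57BL/6J called no gene. For NZO/HlLtJ the smallest p-values belonged to Mir22hg (0.56), Hspa1b (−2.53), Ehd3 (0.28), Gpr146 (0.33) and Dram1 (−0.91), not passing at adjusted p = 0.271. The edgeR count of 0 stood beside 1336 genes at unadjusted p under 0.05, 16 called by DESeq2 and 0 by limma on VST values, and became 6 without C57BL/6J control male 2. For CAST/EiJ they belonged to the exocyst gene Exoc6 (0.34), Gfra1 (0.41), Magi2 (0.28), Id3 (−0.70) and S100a6 (−0.72), not passing at adjusted p = 0.16. Here the edgeR count of 0 stood beside 2041 genes at unadjusted p under 0.05, 26 called by DESeq2 and 0 by limma on VST values. It became 627 without CAST/EiJ control female 2, 2 without C57BL/6J control female 3, 1 without C57BL/6J HFHS female 2 and 1 without CAST/EiJ control male 3.

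Tested jointly over the strains, the diet change differed for 23 genes, led by H1f0, Mir22hg and Hist1h1c (adjusted p = 0.0102), Gfra1 (adjusted p = 0.0183), and S100a6 and Gpr146 (adjusted p = 0.0292). The muscle complex gene Sspn, the DNA repair gene Trp53bp1, Shisa4 and Serpina3n followed (adjusted p = 0.0303). The joint count by edgeR was 0 with the transcript-length covariate and 0 with 2 surrogate variables, with 2358 and 2512 genes at unadjusted p under 0.05, while DESeq2 called 494. It was 1431 without CAST/EiJ control female 2, and 43 and 61 without CAST/EiJ control female 1 and control female 3. Without C57BL/6J control male 2, HFHS female 2 or HFHS female 3 it was 99, 65 and 65, and without NZO/HlLtJ control female 3 or control male 3 it was 52 and 45. It ran from 4 to 15 without any of 18 others and moved by less without HFHS female 2 and HFHS male 3 of NZO/HlLtJ, control male 1 of CAST/EiJ, and control females 1, 2 and 3, control males 1 and 3 and HFHS males 2 and 3 of C57BL/6J. Across all tested genes the correlation of the diet log2 changes was −0.00585 between C57BL/6J and NZO/HlLtJ, −0.0198 between C57BL/6J and CAST/EiJ and −0.0947 between NZO/HlLtJ and CAST/EiJ.

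The feeding peptide genes did not pass for diet in any strain. Agrp, made by hunger neurons of the arcuate nucleus (chr8 105566698–105637393), had log2 changes on HFHS of −0.58 ± 0.29 in C57BL/6J (adjusted p = 1), 0.24 in NZO/HlLtJ (adjusted p = 0.854) and −0.89 ± 0.27 in CAST/EiJ (8.98 ± 4.8 to 4.85 ± 1.77 CPM, adjusted p = 0.113, n = 6 and 6). Npy changed by 0.51 in NZO/HlLtJ (adjusted p = 0.406) and by −0.89 ± 0.22 in CAST/EiJ (36.1 ± 22.1 to 18.8 ± 5.01 CPM, adjusted p = 0.0815). Without CAST/EiJ control female 1, which held 80.1 CPM of Npy, these CAST/EiJ changes were −0.62 for Agrp (adjusted p = 0.408) and −0.56 for Npy (adjusted p = 0.313). Pomc, the satiety precursor gene, changed by 0.35 in C57BL/6J (adjusted p = 1), −0.02 in NZO/HlLtJ (adjusted p = 0.992) and −0.36 in CAST/EiJ (adjusted p = 0.301). The melanocortin receptor gene Mc4r (−0.45, adjusted p = 0.208) and the orexin gene Hcrt (−0.64, adjusted p = 0.401) did not pass in NZO/HlLtJ. Socs3, a leptin feedback gene, was at 5.14 ± 0.983 against 3.58 ± 0.807 CPM in C57BL/6J (0.53 ± 0.16, adjusted p = 1), and the stress peptide gene Crh changed by 0.67 in CAST/EiJ (adjusted p = 0.185). The orexigenic list in CAST/EiJ had a median of −0.21, with 0 called and 2 lower when adjusted over the list alone (adjusted p = 0.00269, and adjusted p = 0.367 with an estimated correlation), and was not called with the transcript-length covariate (adjusted p = 0.421) or 2 surrogate variables (adjusted p = 0.108). In NZO/HlLtJ that list had 0 called and 0 when adjusted over the list alone (adjusted p = 0.426). The leptin and insulin signalling list had 0 called and 0 when adjusted over the list alone in C57BL/6J (adjusted p = 0.728) and in NZO/HlLtJ (adjusted p = 0.0703), and 0 called with 3 higher when adjusted over the list alone in CAST/EiJ (adjusted p = 0.0792).

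**Figure D5:**
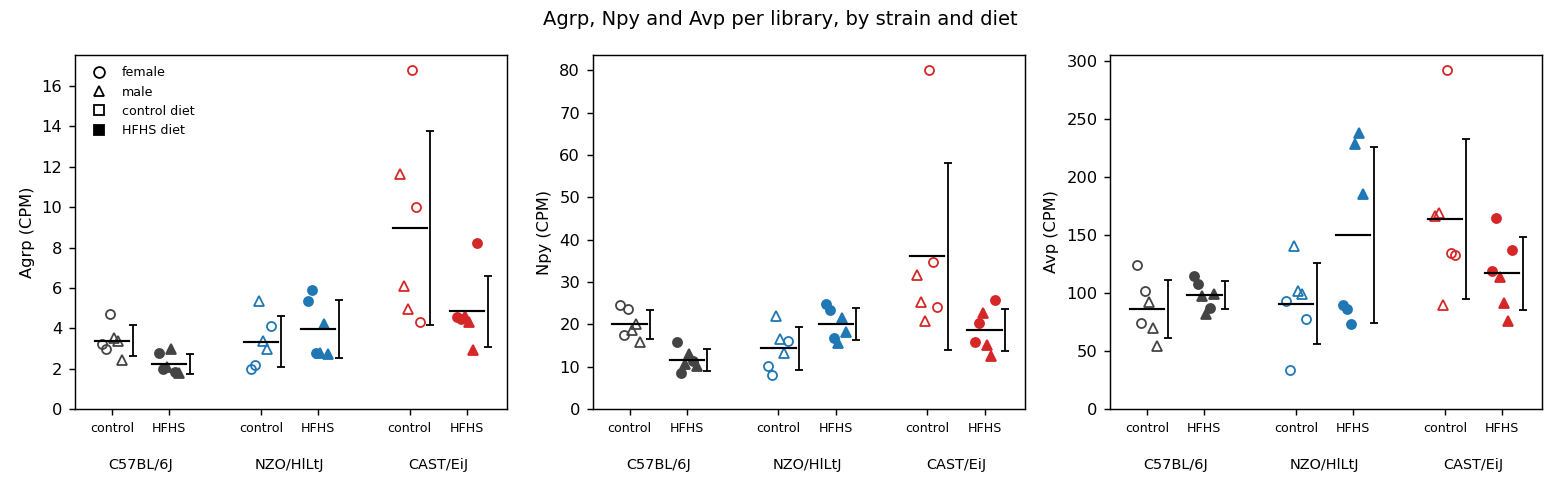
Agrp, Npy and Avp levels by strain and diet. Circles are females and triangles males, open points control diet and filled points HFHS; line, mean; bar, SD of 6 libraries.

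Between NZO/HlLtJ and C57BL/6J on control diet, Wdfy1, C4b and Padi2 were among the genes higher in NZO/HlLtJ and Fggy, Ahcy and Fcrls among those lower. The endosomal gene Wdfy1 (chr1 79702262–79776143) was 3.4-fold higher in NZO/HlLtJ (102 ± 2.84 against 30 ± 3.81 CPM; log2 change 1.77 ± 0.06, adjusted p = 1.74e-20, n = 6 and 6). C4b was 4.44-fold higher (301 ± 65.5 against 68.2 ± 13.6 CPM, adjusted p = 3.23e-17) and Padi2, a protein deiminase gene, 4.83-fold (157 ± 14.3 against 32.5 ± 4.34 CPM, adjusted p = 6.52e-18). The zinc finger gene Zfp949 was 3.09-fold higher, the phospholipase gene Pla2g4e 6.78-fold, the secretory chaperone gene Scg5 2.03-fold and Gabra2 2.26-fold. Lower in NZO/HlLtJ were the carbohydrate kinase gene Fggy (0.113 of the C57BL/6J level; 1.6 ± 0.241 against 14 ± 0.871 CPM, adjusted p = 3.1e-23), the methylation cycle gene Ahcy (0.264; 12.5 ± 1.88 against 47.2 ± 1.13 CPM) and the microglial gene Fcrls (0.113; 1.26 ± 0.405 against 11.5 ± 1.47 CPM). In all, 3555 genes were called, 1693 higher and 1862 lower, 17.7% of those tested, with 881 at 2-fold or more. Loss of NZO/HlLtJ reads in mapping to GRCm38 was not tested, so these are differences in assigned reads. Reactive gliosis genes had a median of 0.677, with 7 called higher and 7 when adjusted over the list alone (adjusted p = 0.00169, and adjusted p = 0.95 with an estimated correlation), among them Gfap at 1.34 and Serpina3n at 0.97 log2. Myelin genes had a median of −0.459, with 14 called lower and 15 when adjusted over the list alone (adjusted p = 2.3e-05, and adjusted p = 0.971 with an estimated correlation), Opalin at −1.01 and Mobp at −0.67. The 13 genes of the mitochondrial genome had a median of −0.39, with 9 called lower and 12 when adjusted over the list alone (adjusted p = 5.46e-06, and adjusted p = 0.971 with an estimated correlation).

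Between CAST/EiJ and C57BL/6J on control diet, Retsat was among the genes higher in CAST/EiJ and Pon2 among those lower. Retsat, the retinol saturase gene, was 7.75-fold higher in CAST/EiJ (116 ± 23.6 against 14.8 ± 0.852 CPM; log2 change 2.95 ± 0.08, adjusted p = 1.03e-23, n = 6 and 6), and Pon2, a paraoxonase gene, fell to 0.0539 of the C57BL/6J level (2.36 ± 0.606 against 43.9 ± 1.74 CPM, adjusted p = 9.25e-24). Wdfy1 was 4.12-fold higher, the glutathione transferase gene Gstm7 4.19-fold, the centrin-binding gene Sfi1 6.72-fold and the cytochrome gene Cyp2d22 2.67-fold. Fam213b, a prostamide synthase gene (chr4 154895504–154899135), was at 0.0292 ± 0.0381 CPM in CAST/EiJ and 42.1 ± 2.04 CPM in C57BL/6J, and the X-linked noncoding gene Firre was at 15.7 ± 3.84 and 118 ± 5.79 CPM. Several of the largest changes, Rpl9, Rpl17, Rpl27-ps3, Rps12-ps3, Tuba1c and Srp54b, have near-identical copies elsewhere and are uncertain in allocation. In all, 8549 genes were called, 4278 higher and 4271 lower, 42.6% of those tested, with 2476 at 2-fold or more. Loss of CAST/EiJ reads in mapping was not tested, so these are differences in assigned reads, also for near-absent genes such as Fam213b. The 24 interferon-induced genes had a median of −0.564, with 3 called higher and 15 lower, and 3 higher and 16 lower when adjusted over the list alone (adjusted p = 0.00128, and adjusted p = 0.993 with an estimated correlation). In it are the antiviral genes Oasl2 (−3.04), Ifit3 (−2.30), Irf7 (−2.17) and, in the other direction, Mx2 (2.81). The antigen presentation list had a median of −0.761, with 1 called higher and 8 lower, and 1 higher and 10 lower when adjusted over the list alone (adjusted p = 0.00409, and adjusted p = 0.993 with an estimated correlation). Ependymal genes had a median of 0.802, with 11 called higher and 2 lower, and the same numbers when adjusted over the list alone (adjusted p = 0.00687, and adjusted p = 0.993 with an estimated correlation). Ribosomal genes had a median of 0.268, with 28 called higher and 3 lower, and 33 higher and 3 lower when adjusted over the list alone (adjusted p = 5.58e-06, and adjusted p = 0.993 with an estimated correlation). The library of CAST/EiJ control female 1 stood 1.47 log2 above the other CAST/EiJ libraries in ependymal genes and 0.71 in ribosomal genes, and without it both the ependymal markers (adjusted p = 0.00183) and the ribosomal proteins (adjusted p = 0.000973) were still called higher.

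Between NZO/HlLtJ and CAST/EiJ on control diet, Mttp and Pon2 were among the genes higher in NZO/HlLtJ and Retsat among those lower. The lipoprotein assembly gene Mttp was 3.16-fold higher in NZO/HlLtJ (37.1 ± 2.35 against 11.7 ± 0.594 CPM; log2 change 1.66 ± 0.05, adjusted p = 3.05e-21, n = 6 and 6), as was Pon2 at 13.6-fold. Retsat stood at 0.132 of the CAST/EiJ level, Cyp2d22 at 0.348 (28 ± 1.23 against 80.6 ± 9.94 CPM) and Madd, a vesicle trafficking gene, at 0.342 (24.1 ± 0.898 against 70.5 ± 7.22 CPM, adjusted p = 4.23e-20). In all, 8611 genes were called, 4249 higher and 4362 lower, with 2492 at 2-fold or more. Interferon-induced genes had a median of 0.897, with 20 called higher and 2 lower, and the same numbers when adjusted over the list alone (adjusted p = 1.27e-06, and adjusted p = 0.987 with an estimated correlation). The 650 pseudogenes were 3.24% of tested genes and made up 3.21%, 3.61% and 3.55% of all calls and 26.2%, 25.7% and 25.9% of calls with a log2 change of 4 or more in NZO/HlLtJ against C57BL/6J, CAST/EiJ against C57BL/6J and NZO/HlLtJ against CAST/EiJ.

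Among the fixed feeding genes on control diet, Agrp, Npy and Hcrt were higher in CAST/EiJ than in C57BL/6J, while Pomc did not pass in any strain contrast. In CAST/EiJ, Agrp was 2.63-fold above C57BL/6J (8.98 ± 4.8 against 3.39 ± 0.755 CPM, adjusted p = 0.000126, n = 6 and 6), Npy 1.74-fold (36.1 ± 22.1 against 20 ± 3.44 CPM, adjusted p = 0.00384), Hcrt 2.26-fold (117 ± 63 against 48.7 ± 23.3 CPM, adjusted p = 0.000841) and the melanin-concentrating hormone gene Pmch 1.75-fold (adjusted p = 7.15e-05). Avp, the vasopressin gene (chr2 130580620–130582554), was 1.91-fold higher there (164 ± 68.9 against 86.2 ± 24.9 CPM, adjusted p = 0.000488), and Crh stood at 0.485 of the C57BL/6J level (adjusted p = 0.0015). The CAST/EiJ means include control female 1, with 80.1 CPM of Npy against 20.9–34.7 CPM in the other 5 and 292 CPM of Avp against 89.9–169 CPM. Without it the log2 change from C57BL/6J was 0.46 for Npy (adjusted p = 0.0439) in place of 0.80, 1.12 for Agrp in place of 1.40, 0.97 for Hcrt in place of 1.18 and 0.69 for Avp in place of 0.93, all still called. In NZO/HlLtJ against C57BL/6J, Cartpt, a satiety peptide gene, was 1.66-fold higher (62.1 ± 2.81 against 37.5 ± 6.53 CPM, adjusted p = 1.77e-05), Pmch 1.54-fold (adjusted p = 0.00333), Mc4r 1.41-fold (adjusted p = 0.0112) and Socs3 1.94-fold (6.9 ± 1.63 against 3.58 ± 0.807 CPM, adjusted p = 4.18e-05). Agrp (−0.03 log2, adjusted p = 0.971), Npy (−0.50, adjusted p = 0.125) and Pomc (0.06, adjusted p = 0.873) did not pass in that contrast. Against CAST/EiJ, NZO/HlLtJ had Agrp at 0.374 of its level (adjusted p = 9.03e-05), Npy at 0.406 (adjusted p = 1.79e-05) and Socs3 2.09-fold higher (adjusted p = 2.66e-06). Without CAST/EiJ control female 1 the log2 change was −0.96 for Npy in place of −1.30 and −1.15 for Agrp in place of −1.42. Pomc did not pass in CAST/EiJ against C57BL/6J (0.28 log2, adjusted p = 0.207) or in NZO/HlLtJ against CAST/EiJ (−0.22, adjusted p = 0.327).

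In C57BL/6J, Socs2, Cish, Esr1 and immediate early genes were higher in females. Socs2, a growth hormone feedback gene, was 1.9-fold higher in females (15.3 ± 3.57 against 8.04 ± 1.41 CPM; log2 change 0.92 ± 0.13, adjusted p = 8.33e-05, n = 6 and 6), Cish 1.67-fold (adjusted p = 0.000822) and the estrogen receptor gene Esr1 1.73-fold (37.2 ± 11 against 21.6 ± 2.45 CPM, adjusted p = 0.00155). The immediate early genes Nr4a1 (2.99-fold; 58.9 ± 30 against 21.2 ± 13 CPM, adjusted p = 0.00283) and Junb (2.35-fold, adjusted p = 0.0167) and the clock gene Per1 (1.5-fold; 112 ± 16.2 against 75.4 ± 16 CPM, adjusted p = 0.00413) were higher, as were Arid5a (0.70 log2, adjusted p = 0.00232), Apold1 (1.53, adjusted p = 0.0025), Dnajb5 (0.41, adjusted p = 0.00972) and Adamts1 (0.63, adjusted p = 0.0171). Kiss1, encoding kisspeptin, changed by 1.90 ± 0.41 log2 (adjusted p = 0.0387). Of 39 called genes, 31 higher and 8 lower in females, 25 were autosomal. The count was 25, 23, 81 and 24 without HFHS female 1, HFHS female 2, HFHS female 3 and control male 3. With a term for library number, added after the data were seen, 15 genes were called and none of the autosomal genes named here was among them, with Socs2 at 0.61 and Esr1 at 0.63 log2. The dividing point of that term was chosen from immediate early levels and overlaps with sex. The 20 immediate early genes had a median of 1.15, with 7 called higher and 18 when adjusted over the list alone (adjusted p = 2.86e-39, and adjusted p = 0.00506 with an estimated correlation). Glucocorticoid-induced genes had a median of 0.528, with 1 called higher and 14 when adjusted over the list alone (adjusted p = 1.78e-19, and adjusted p = 0.0352 with an estimated correlation). These 2 groups moved with the numbering of the libraries: the mean log2 score of the immediate early list was 0.52–1.36 in the 7 lower-numbered C57BL/6J libraries, 5 of them female, and −0.62–0.12 in the 5 higher-numbered ones, 4 of them male. With the library number term the glucocorticoid response was not called (adjusted p = 0.291), nor were the blood cell markers (adjusted p = 0.585). Blood genes had a median of 0.733, with 0 called and 5 higher when adjusted over the list alone (adjusted p = 2.78e-07, and adjusted p = 0.114 with an estimated correlation).

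In NZO/HlLtJ, vasopressin was lower in females. Avp was at 75.6 ± 22 CPM in females against 165 ± 61.1 CPM in males, a log2 change of −1.06 ± 0.21 (adjusted p = 0.0231, n = 6 and 6). It was at 68.2 ± 31.1 and 83 ± 8.57 CPM in control and HFHS females and at 114 ± 23 and 217 ± 28.2 CPM in control and HFHS males (n = 3 each). Avp was the only autosomal gene among the 14 called for sex in this strain. It was no longer called without control female 2, control male 1, HFHS female 1, HFHS female 3, HFHS male 1 or HFHS male 2, with log2 changes of −0.90, −0.98, −1.09, −1.02, −1.04 and −1.03 in that order. Genes of cortex, hippocampus and striatum, 17 in number, were higher in females with a median of 0.142, 0 called and 1 when adjusted over the list alone (adjusted p = 0.0119, and adjusted p = 0.0372 with an estimated correlation). Mitochondrial genome transcripts had a median of 0.15, with 0 called and 0 when adjusted over the list alone (adjusted p = 2.41e-05, and adjusted p = 0.823 with an estimated correlation).

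In CAST/EiJ, Ctss, Gpx1 and C4b were among the genes higher in females and Nbr1 among those lower. The protease gene Ctss was 1.27-fold higher (39.3 ± 7.72 against 30.9 ± 1.99 CPM; log2 change 0.34 ± 0.07, adjusted p = 0.0329, n = 6 and 6), the antioxidant gene Gpx1 1.21-fold (53.9 ± 9.65 against 44.3 ± 2.48 CPM, adjusted p = 0.0246) and C4b 1.35-fold (134 ± 24.2 against 98.6 ± 6.7 CPM, adjusted p = 0.0337), with the lysosomal membrane gene Lamp1 at 374 ± 51.8 against 321 ± 5.47 CPM (adjusted p = 0.0318). Nbr1, an autophagy receptor gene, stood at 0.693 of the male level (204 ± 10.2 against 303 ± 99.1 CPM, adjusted p = 0.000179), and Tmem106a on the same chromosome, 11, at 0.58 (3 ± 0.558 against 5.3 ± 1.74 CPM, adjusted p = 0.0246). Of 37 called genes, 21 higher and 16 lower in females, 19 were autosomal. Without control female 2 the count was 3088. It was 16, 18, 22, 16, 24, 20, 16 and 23 without control female 1, control male 2, control male 3, HFHS female 1, HFHS female 2, HFHS female 3, HFHS male 1 and HFHS male 2. Without control female 1, Ctss, Gpx1, Lamp1 and C4b were among the genes no longer called. The 20 microglial genes had a median of 0.217, with 1 called higher and 9 when adjusted over the list alone (adjusted p = 3.9e-07, and adjusted p = 0.61 with an estimated correlation). Their mean log2 level was 0.384 in control female 1, 0.102 in control female 3 and −0.286 to −0.071 in the other 10 CAST/EiJ libraries. Ribosomal genes had a median of 0.206, with 0 called and 30 higher when adjusted over the list alone (adjusted p = 1.19e-14, and adjusted p = 0.61 with an estimated correlation), and oxidative phosphorylation genes 0.157, with 0 called and 24 higher when adjusted over the list alone (adjusted p = 8.78e-13, and adjusted p = 0.61 with an estimated correlation). Both groups stood highest in the library of control female 1, and neither the ribosomal proteins (adjusted p = 0.93) nor oxidative phosphorylation (adjusted p = 0.992) was called with the transcript-length covariate. With 2 surrogate variables the microglia markers were not called (adjusted p = 0.0715).

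Sex-linked genes moved as a list in each strain, with the members split by chromosome. The 10 Y-linked and X-escape genes had 5 called higher and 4 lower in C57BL/6J (adjusted p = 4.43e-12, adjusted p = 0.00506 with an estimated correlation), 6 and 4 in NZO/HlLtJ (adjusted p = 1.83e-13, and adjusted p = 0.00174 with an estimated correlation) and 5 and 4 in CAST/EiJ (adjusted p = 8.52e-10, and adjusted p = 0.0369 with an estimated correlation). When adjusted over the list alone, 6 were higher and 4 lower in each strain. The camera test called the list lower in females and the mean log2 change was −2.71, −2.65 and −3.05, while the median was above 0 at 0.425, 0.412 and 0.313. In CAST/EiJ it was not called with 2 surrogate variables (adjusted p = 0.181). In C57BL/6J, Xist changed by 11.41 log2, Kdm5d by −8.64, Eif2s3x by 0.58 and Ddx3x by 0.51.

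The sex difference was not called as different between strains for any gene. Nbr1 and Avp had the smallest p and did not pass (adjusted p = 0.122), nor did Mid1, Per1 and Arid5a (adjusted p = 0.222). The edgeR count of 0 stood beside 2378 genes at unadjusted p under 0.05, 27 called by DESeq2 and 1 by limma on VST values. It was 971 without CAST/EiJ control female 2, 16 without C57BL/6J HFHS female 3, 4 without C57BL/6J control male 1, and 1 without C57BL/6J control female 2 or without CAST/EiJ control male 1, control male 2, HFHS female 2 or HFHS male 2. The diet change differed by sex for 1 gene, Serpina3n (adjusted p = 0.021). In NZO/HlLtJ it was at 65.5 ± 12 CPM in control females and 170 ± 22.8 CPM in HFHS females, and at 104 ± 17.6 and 100 ± 13 CPM in control and HFHS males (n = 3 each). In C57BL/6J it was at 39.7 ± 5.02 and 44.3 ± 8.94 CPM in control and HFHS females and 45.1 ± 6.05 and 69.2 ± 6.42 CPM in males. The count of 1 became 0 without NZO/HlLtJ control female 1, control female 2, control male 2, control male 3, HFHS female 1, HFHS female 2, HFHS male 1 or HFHS male 2. It became 2 without CAST/EiJ control male 3, CAST/EiJ HFHS male 2 or C57BL/6J HFHS male 3, and 73 without CAST/EiJ control female 2.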

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

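The diet contrasts between strains and between sexes and the screen for libraries that stand apart were planned, and the tests of the CAST/EiJ control female 1 library against pituitary content and transcript length, like the fits without it, were chosen only after its levels were seen.

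The genes here come from tests of the difference in diet change between strains or between sexes. Between NZO/HlLtJ and CAST/EiJ 361 genes were called, with differences in log2 change of 0.50 for H1f0, 1.10 for Hist1h1c, 0.69 for Mir22hg, 0.76 for Sspn, 0.53 for Shisa4, 0.91 for the carbonic anhydrase gene Car14, 0.85 for Serpina3n, 0.82 for S100a6, 1.14 for Cidea and 0.39 for Gpr146. In the other direction stood Gfra1 at −0.49, Trp53bp1 at −0.35, the substance P receptor gene Tacr1 at −0.65, the potassium channel gene Kcnh1 at −0.42, Reln at −0.69, Dtx4 at −0.33, Elfn1 at −0.48, Magi2 at −0.28 and Hpcal4 at −0.37. Only 1 of 100 splits of the diet labels, the real one, called as many genes as 361, and the highest of the others called 6, so chance can be excluded for that count. The count was 37 with the transcript-length covariate and 45 with 2 surrogate variables, and CAST/EiJ control female 1 and control female 3 carried length slopes of −0.239 and −0.116. H1f0, Hist1h1c, Mir22hg and Gfra1 stayed called under both, and Reln, Dtx4 and Magi2 under neither. The joint test over 3 strains called 23 genes, reached by 1 of 100 splits, the real one, with 9 as the highest of the others. By edgeR that joint count was 0 with the length covariate and 0 with 2 surrogate variables (2358 and 2512 genes at unadjusted p under 0.05), and DESeq2 called 494. The joint test of diet by sex called 1 gene, Serpina3n, and 13 of 100 splits called as many, the highest of the others 5, so chance cannot be excluded there and a difference between the sexes is not established. That count was 0 without any of 8 NZO/HlLtJ libraries named in the report.

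Libraries were screened within groups of 6 for a value set apart from the rest by a gap that is wide against the group's range, in 47 tests of which chance would pick about 1 in 20. NZO/HlLtJ HFHS female 2 had 46.3 M counts, against 32.7–37.5 M in the other 5. NZO/HlLtJ HFHS male 3 had 19 CPM of Fos against 12.8–15.1 CPM. C57BL/6J HFHS male 3 had 2.44 CPM of Gh against 0–0.0584 CPM, and CAST/EiJ HFHS female 3 had 3.29 CPM against 0–0.206 CPM. The genes screened were Hbb-bs, Hspa1b, Fos, Gfap, Serpina3n and Gh, beside total count and mitochondrial share. Of these genes, CAST/EiJ control female 1 stood out in 3, with 743 CPM of Gfap against 194–279 CPM, 97.4 CPM of Serpina3n against 53.1–69.4 CPM and 802 CPM of Gh against 0.252–116 CPM.

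The library of CAST/EiJ control female 1 held pituitary transcripts (Prl 1331 CPM, Cga 241.7 CPM) and stood above the other CAST/EiJ libraries in ependymal genes by a median of 1.47 log2, in myelin genes by 1.14 and in ribosomal genes by 0.71. Pituitary tissue in the sample is argued against as the whole cause, because the median absolute deviation over 12652 abundant genes outside the pituitary list was 0.29 log2, against 0.14 in the next library, control female 3. Transcript length explained 24.5% of the variance of its deviation, and whether length bias, a different piece of tissue or both are behind it cannot be told apart with 1 library. A biological cause, such as a true difference of this animal, was not tested. With this library left out, diet in CAST/EiJ called 9 genes in place of 24, with Hbb-bs, Hba-a2, Hbb-bt, Alas2 and Ube2l6 among them.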

How the results depend on the processing

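These 4 alternatives were chosen only after the data were seen: the fit without the pituitary-rich library, the library number term, the red-cell level covariate and the transcript-length covariate. The red-cell covariate is built from globin genes and Alas2, so it cannot speak on the calls of those genes. It also ended calls of other genes. The count for diet in NZO/HlLtJ, where no red-cell gene was named, went from 29 to 5. Of 248 called gene results under 6057 alternative fits, 5480 kept their call, 576 lost it and 1 reversed, Fam46c for diet in CAST/EiJ, at 0.1 with the red-cell covariate. Of 423 not called, under 11479 fits, 251 became calls. The losses listed next include the reversal. CAST/EiJ control female 1 enters them both as a library left out and as the pituitary-rich library. Losses came from leaving out 1 library (371), 2 surrogate variables (37), the red-cell (37) and length covariates (31), the fit without the pituitary-rich library (23), an additive sex term (17), the libraries compared alone (13), the number term (12), limma on VST (12), DESeq2 (9), no filter (9), median-ratio size factors (3) and leaving out abundant genes (3).

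Counts that moved by over 1.5 times follow, against reported edgeR counts for diet of 0 in C57BL/6J (687 at unadjusted p under 0.05), 29 in NZO/HlLtJ, 24 in CAST/EiJ and 6 averaged, for diet differences of 0 (1336), 0 (2041), 361 and 23 jointly, for sex of 39, 14 and 37, for sex by strain of 0 (2378) and for diet by sex of 1. With DESeq2 diet called 3 genes in C57BL/6J, 153 in NZO/HlLtJ, 420 in CAST/EiJ and 17 averaged. The strain differences of diet were 16 (NZO/HlLtJ against C57BL/6J), 26 (CAST/EiJ against C57BL/6J), 918 (NZO/HlLtJ against CAST/EiJ) and 494 (joint), sex was 76 in C57BL/6J and 512 in CAST/EiJ, sex by strain 27 and diet by sex 8. With no filter diet was 13 in CAST/EiJ and the difference from NZO/HlLtJ 236, and with the strict filter the joint count was 68. With an additive sex term diet was 16 in NZO/HlLtJ, 12 in CAST/EiJ, their difference 178 and the joint count 6. With 2 surrogate variables diet was 9 in CAST/EiJ, the difference from NZO/HlLtJ 45, the joint count 0 and sex in CAST/EiJ 21. On the libraries compared alone, diet was 173 in NZO/HlLtJ and 6 in CAST/EiJ. Without the pituitary-rich library diet was 98 in NZO/HlLtJ and 9 in CAST/EiJ, the joint count 43 and sex in CAST/EiJ 16. With the red-cell covariate diet was 5 in NZO/HlLtJ, 4 in CAST/EiJ and 0 averaged, and the joint count 66. With the length covariate diet was 80 in NZO/HlLtJ and 7 in CAST/EiJ, their difference 37, the joint count 0, sex in CAST/EiJ 20 and sex by strain 1. With the number term diet in C57BL/6J was 2 and sex 15. With limma on VST sex by strain was 1. Counts at 2-fold or more between strains were 881, 2476 and 2492, and autosomal counts for sex 25, 1 and 19.

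Reported list counts were 13, 13, 22 and 15 for diet, 7, 7 and 5 for the strains and 13, 5 and 14 for sex. Called lists with an estimated correlation were 0, 1, 1 and 1 for diet (C57BL/6J, NZO/HlLtJ, CAST/EiJ, averaged), 1, 0 and 0 for the strains and 3, 2 and 1 for sex. With the rotation test fry of limma they were 0, 1, 1 and 1 for diet, 20 and 16 for the 2 strain contrasts with CAST/EiJ, and 3, 2 and 1 for sex. With the red-cell covariate 13 were called in CAST/EiJ and 9 averaged. With 2 surrogate variables they were 3 for NZO/HlLtJ against CAST/EiJ, 8 for sex in NZO/HlLtJ and 3 in CAST/EiJ, with the length covariate 3 for NZO/HlLtJ against CAST/EiJ, and with the number term 5 for sex in C57BL/6J. The correlation of diet changes between C57BL/6J and NZO/HlLtJ was 0.0557 with the strict filter, 0.077 on VST and 0.0241 with surrogate variables. Between C57BL/6J and CAST/EiJ it was 0.00836 with the strict filter, 0.0422 on VST and −0.045 with the length covariate. Between NZO/HlLtJ and CAST/EiJ it was −0.246, −0.262, −0.115 and −0.0677 with the strict filter, VST, surrogate variables and the pituitary-rich library left out.

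With each library that enters a contrast left out in turn, counts ran from 0 to 2 for diet in C57BL/6J, 7 to 36 in NZO/HlLtJ and 7 to 2681 in CAST/EiJ. Libraries outside a contrast are not in these ranges. The diet differences ran from 0 to 6 and 0 to 627 against C57BL/6J, 78 to 2211 between the other strains and 4 to 1431 jointly. Sex ran from 23 to 81 in C57BL/6J and 16 to 3088 in CAST/EiJ, sex by strain from 0 to 971 and diet by sex from 0 to 73. Called lists ran from 7 to 16 for diet in C57BL/6J (7 without HFHS male 3), 3 to 9 for sex in NZO/HlLtJ (3 without control female 2 or HFHS female 2, 9 without control male 3) and 9 to 16 for sex in CAST/EiJ (9 without control male 1). Correlations ran from −0.0349 to 0.0353, −0.0446 to 0.0122 and −0.117 to −0.0414 in the order above. Among the libraries that enter a contrast, those behind the changes in gene counts are named beside the results in the report. The widest swings, all upward, came when CAST/EiJ control female 2 was left out. Its group then held only control female 1 and control female 3, with length slopes of −0.239 and −0.116, against 0.0365 in control female 2. Whether those slopes are behind the swings was not tested.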

Other observations

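Tests chosen only after the result was seen are both tests of library number and that of lower tissue temperature for the heat shock genes, the library number term in C57BL/6J, and the reading of the white-cell and platelet markers as undecided; the immediate early covariate, the length covariate for red-cell transcripts and the splits of the labels were written before.

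Cold-induced RNA-binding genes moved opposite to the heat shock genes in NZO/HlLtJ, without passing. Cirbp ran from 75.4 to 85.2 CPM in the 6 HFHS libraries and from 48.9 to 69.3 CPM in the 6 controls, a log2 change of 0.46 with SE 0.11 (adjusted p = 0.111). Rbm3 changed by 0.26 with SE 0.12 (adjusted p = 0.462). In CAST/EiJ, Cirbp lay the other way, at 39.2–53.8 CPM on HFHS and 49.9–70.2 CPM on control diet. Hspa1b there had a median of 11.8 CPM on HFHS (9.07–18.2) and 22.2 CPM on control diet (4.24–28.7). Opposite movement of Hspa1b and Cirbp was therefore not seen in that strain. Both genes were chosen after their values were seen.

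The lower heat shock transcripts in NZO/HlLtJ on HFHS were weighed against arousal, library number and temperature. Arousal or handling, marked by the immediate early genes, is argued against as the whole cause: with the immediate early level as a covariate 77.3% of the list's mean log2 change remained (−0.64 with SD 0.65 over genes before, −0.49 with SD 0.55 after), and Hspa1b still changed by −2.13. A trend or a single divide in library number is argued against, since the diets alternate in 4 blocks of numbers and the lowest later-numbered control stood 0.35 log2 above the highest HFHS library numbered before it, with all 6 controls (0.06 to 0.55) above all 6 HFHS libraries (−0.40 to −0.28). Handling in blocks that coincide with diet cannot be told apart from diet: in the lower run the HFHS level was lower by 0.63, with all control numbers before all HFHS numbers. A lower tissue temperature on HFHS, or a higher one in the controls, stays open as a candidate explanation, since both Cirbp and Rbm3 moved upward, the lesser by 0.26 log2, though neither passed. As a hypothesis this can be tested by recording brain temperature before tissue collection in new NZO/HlLtJ animals on both diets, with the prediction that Hspa1b rises and Cirbp falls with temperature within each diet.

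The lower red-cell transcripts in CAST/EiJ on HFHS were weighed against 2 technical explanations. Short transcripts being high in some control libraries is argued against: with the length slope as a covariate the mean log2 change of the 4 red-cell genes was −2.14 with SD 0.12 and 4 of 4 stayed called. Less blood in the tissue cannot be decided. The white-cell and platelet markers changed by a mean of −1.07 with SE 0.48, smaller than the red-cell mean of −2.03 with SE 0.04. With these values the bound written before for arguing against less blood was met. The red-cell SE holds only the spread over the 4 genes, without each gene's own error. It is therefore too small, and the bound decides nothing. Also, 7 of the 8 markers averaged under 1 CPM, a reading made after the value was seen. The other marker, Itga2b at 3.44 CPM, changed by 0.022 log2 with SE 0.129, and 1 gene cannot decide. Less residual blood in the tissue and fewer young red cells in the circulation both stay possible. As a hypothesis the latter predicts, on reticulocyte counts of new CAST/EiJ animals, a lower count on HFHS with no difference in perfused tissue.

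Within C57BL/6J, immediate early, glucocorticoid-induced and blood genes moved with library number. The glucocorticoid score was 0.05–0.73 in the 7 lower-numbered libraries and −0.66 to −0.21 in the 5 higher-numbered ones. The point that separates them was chosen after these levels were seen, so it follows the outcome and is no independent batch. It overlaps with sex and with diet. Of the higher-numbered libraries only control male 3 was on control diet, and of the lower-numbered ones only HFHS female 1 and HFHS female 2 were on HFHS. With a term for it, the immediate early list turned from lower to higher on HFHS (adjusted p = 3.9e-06), as did the glucocorticoid list (adjusted p = 0.00512), and the blood list was no longer called (adjusted p = 0.898). For sex, the immediate early genes stayed higher as a list in females (adjusted p = 2.21e-07), and the glucocorticoid list (adjusted p = 0.291) and blood list (adjusted p = 0.585) were no longer called. The count for sex was 15 in place of 39, Socs2 changed by 0.61 in place of 0.92 log2 and Nr4a1 by 0.89 in place of 1.58. Since the dividing point follows the outcome and 4 of the 5 higher-numbered libraries are male, a fall in these values was built into the fit, which decides nothing between order of handling, sex and diet.

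Real counts were set beside other splits of the same labels, with 100 splits per result, the real one included. For diet in CAST/EiJ 24 genes were called, with 1 split as large, the real one, and 10 in the highest other. The count was 9 without control female 1, 9 with 2 surrogate variables and 7 with the transcript-length covariate. No splits were run on those fits, so chance is made unlikely for the count of 24 but is not firmly excluded. For diet in NZO/HlLtJ (29 genes, 2 splits as large) the share lay under 0.05. Another split called 50 genes there, more than the real one, so chance is made unlikely but is not excluded. For diet averaged over the strains (6 genes, 3 splits) the highest other split called 636, many times the real count, which points to a structure of the samples other than diet, and what that structure is was not tested. For results with a real count of 0, every split is as large by construction, so the splits decide nothing: these are diet in C57BL/6J (highest other of 100 splits 14), the diet change of NZO/HlLtJ and of CAST/EiJ against C57BL/6J (16 and 6) and sex by strain (7). Those 4 zero counts came from edgeR, with 687, 1336, 2041 and 2378 genes at unadjusted p under 0.05, 3, 16, 26 and 27 called by DESeq2 and 0, 0, 0 and 1 by limma on VST values. For sex in C57BL/6J (39 genes, 1 split, highest other 24), NZO/HlLtJ (14, 1 and 2) and CAST/EiJ (37, 1 and 5) the splits decide nothing on the autosomal genes, because X-linked and Y-linked genes are called under the true labels whatever the rest do. The autosomal counts were 25, 1 and 19, and no splits were run on them alone. Chance can be excluded for NZO/HlLtJ against C57BL/6J (3555, 1 and 1), CAST/EiJ against C57BL/6J (8549, 1 and 26) and NZO/HlLtJ against CAST/EiJ (8611, 1 and 3).

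For counts of called lists, the real split was the largest only for diet in CAST/EiJ (22 lists, 1 split of 100, highest other 21). That margin is small. The count was 16 with the transcript-length covariate, with 2 surrogate variables or without control female 1, so chance is not firmly excluded. Chance cannot be excluded for diet in C57BL/6J (13 lists, 24 splits, highest other 20), NZO/HlLtJ (13, 39 and 22) or averaged over the strains (15, 27 and 22). Nor can it for sex in C57BL/6J (13, 24 and 19), NZO/HlLtJ (5, 81 and 16) and CAST/EiJ (14, 33 and 18), or for NZO/HlLtJ against C57BL/6J (7, 83 and 23), CAST/EiJ against C57BL/6J (7, 88 and 24) and NZO/HlLtJ against CAST/EiJ (5, 92 and 20). The median counts of the other splits, in the same order, were 13 for diet in CAST/EiJ, then 9, 11 and 11 for diet, 9, 8 and 13 for sex and 10, 11 and 10 for the strains.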
